A study of Mus musculus with 6 samples.

How the data were processed

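RNA sequencing was done on epididymal white adipose tissue in 6 mouse samples, 3 with a myeloid-specific PD-1 deletion and 3 littermate controls, after 16 weeks of high-fat diet. Per the labels' protocols, mRNA was purified from total RNA, fragmented and made into amplified cDNA libraries. Reads were processed, per the submitters' processing notes, with fastp (version not given there), HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 on build mm10. The strand setting, counting parameters and annotation release are not given in the sources used here, so reads of overlapping, antisense or paralogous genes, such as Mup and hemoglobin genes, cannot be separated with certainty. The authors deposited a table of raw counts per gene and library, with whole numbers for 54532 gene identifiers, and this count table was used for the tests. The authors also deposited FPKM values, which within a library are proportional to the counts of each gene but carry a library scale of the authors' own, between 0.526 and 1.21 times that of total counts relative to control replicate 1. FPKM served for alternatives alone.

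Library totals were 20108185 to 27225533 counts. Gene symbols were matched for 54409 identifiers, and coordinates are those of GENCODE vM21 on GRCm38, the same assembly as mm10. A gene with fewer than 3 counts in a library was taken as at the floor. Shares of counts have exact Clopper-Pearson intervals at 95%, which cover counting error only. Replicates were compared before averaging, and chi-square per degree of freedom between pairs was 62.4 to 1235, so each library was counted as its own sample.

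Genes were tested with edgeR 4.0.16 (R 4.3.3), quasi-likelihood with robust fits, on genes kept by filterByExpr by group, with TMM scaling (factors 0.559 for control replicate 2 and 0.982 to 1.25 for the others) and Benjamini-Hochberg adjustment at 0.05, for 15928 genes with all 6 libraries and 16729 without control replicate 2. Standard errors are the fold change over the root of the F statistic. CPM values are scaled by TMM. Gene lists were fixed before the data were examined, 42 lists, of which 39 had at least 5 tested members; 576 of 579 genes were found. They were tested with limma 3.58.1 camera on log CPM (prior count 2) with a preset correlation of 0.01, with adjustment over the lists, and with an estimated correlation and fry as alternatives. List means use log2(CPM + 1). The calls with the preset correlation, with all 6 libraries or without control replicate 2, did not hold with an estimated one, and the other settings were run with the preset correlation alone. A list of 16 hepatocyte genes was added after the data were seen, as was a set of 171 liver genes with at least 200 CPM in control replicate 2 and at most 0.5% of that level in knockout replicate 1 and control replicate 1.

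Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors, other filters, FPKM with pseudocounts of 1 and 0.1, thresholds, the title number as a term, and each library left out in turn; others were added after control replicate 2 was seen to hold liver transcripts. The title number term set knockout replicate 3 and control replicate 3 apart from the other libraries. With 3 against 3 libraries an exact two-sided permutation test cannot go below 0.1. The labels give no replicate numbers, so replicates are numbered in the order of the sample records and no pairing was used.

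Genes named are PD-1 pathway and stress genes fixed in advance (Pdcd1, Lyz2, Cd274, Pdcd1lg2, Ulk1, Fbxo38, Ern1, Xbp1, Hspa5, Ddit3), then the largest fold changes among genes past the threshold with mean log CPM of at least 1, a real symbol and no overlap between groups, or, as here where no gene passed, the 6 of smallest p per direction meeting the other conditions, and up to 4 members of smallest p per list. Adipoq, Alb, Plin1, Mup22 and the other liver or single genes of tissue origin were chosen after their values were seen. The tests were checked on counts simulated from these libraries with 200 genes changed. With the estimated dispersion and all 6 libraries, edgeR called 0 of 50 genes at each of 2-, 4-, 8- and 16-fold. Without control replicate 2 it called 0, 18, 41 and 48 of 50 with 11 of 16509 unchanged genes. DESeq2 called 4, 15, 41 and 48 of 50 and 101 of 15708 unchanged genes with all 6. Without control replicate 2 it called 5, 36, 46 and 49 of 50 and 80 of 16509 unchanged genes. Camera found a list shifted 2-fold (p 1.25e-05 preset, 0.0125 estimated) and not an unchanged list (0.541 and 0.645). Simulated genes were drawn independently of each other, whereas the estimated correlation was 0.737 for the real macrophage list. This check therefore cannot show whether the preset correlation suits the real lists. Figures were drawn with matplotlib 3.10.9.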

Results

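Gene expression was measured by RNA sequencing in epididymal white adipose tissue, the fat pad beside the epididymis, of mice (Mus musculus) fed a high-fat diet for 16 weeks. PD-1, encoded by Pdcd1, is an inhibitory receptor best known on T cells. In the knockout group it was deleted by a Cre recombinase expressed from the Lyz2 locus, which is active in macrophages and other myeloid cells. The control group consisted of littermates with the floxed gene and no Cre. Each group held 3 libraries. Total counts were 25441746, 22813206 and 24045097 in knockout replicates 1 to 3 and 27225533, 20108185 and 24252066 in control replicates 1 to 3. Replicates are numbered here in the order of the sample records, so that control replicate 2 is the library titled HF_7690_eWAT. Sample titles carry different numbers, but the labels do not state that each library came from its own animal, so the p-values measure the spread between these samples.

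Control replicate 2 had a liver profile. Alb, the gene of serum albumin made by hepatocytes, took 8.27% of its counts (95% exact Clopper-Pearson interval 8.25% to 8.28%). In control replicate 3 Alb took 0.436% (0.434% to 0.439%), in knockout replicate 2 0.0817% (0.0806% to 0.0829%) and in knockout replicate 3 0.00617% (0.00586% to 0.00649%). Knockout replicate 1 and control replicate 1 had 0.000483% (0.000402% to 0.000577%) and 0.000724% (0.000626% to 0.000832%), and these intervals cover counting error only. A list of 16 hepatocyte genes, chosen after the data were seen, averaged 12.96 log2(CPM + 1) in control replicate 2, 8.05 in control replicate 3, 5.55 in knockout replicate 2, 1.98 in knockout replicate 3 and 0.55 and 0.52 in knockout replicate 1 and control replicate 1. The 14-gene adipocyte list averaged 6.02 in control replicate 2 and 9.39 to 10.6 in the 5 other libraries. Adipoq, which encodes the fat hormone adiponectin, stood in control replicate 2 at 0.65% of its median in the 5 other libraries, Lep (leptin) at 0.841% and Plin1, a lipid droplet protein, at 1.05%. The first principal component carried 69.4% of the variance and placed this library at 269.6, with the others between −94.6 and 4.76.

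**Figure D1:**
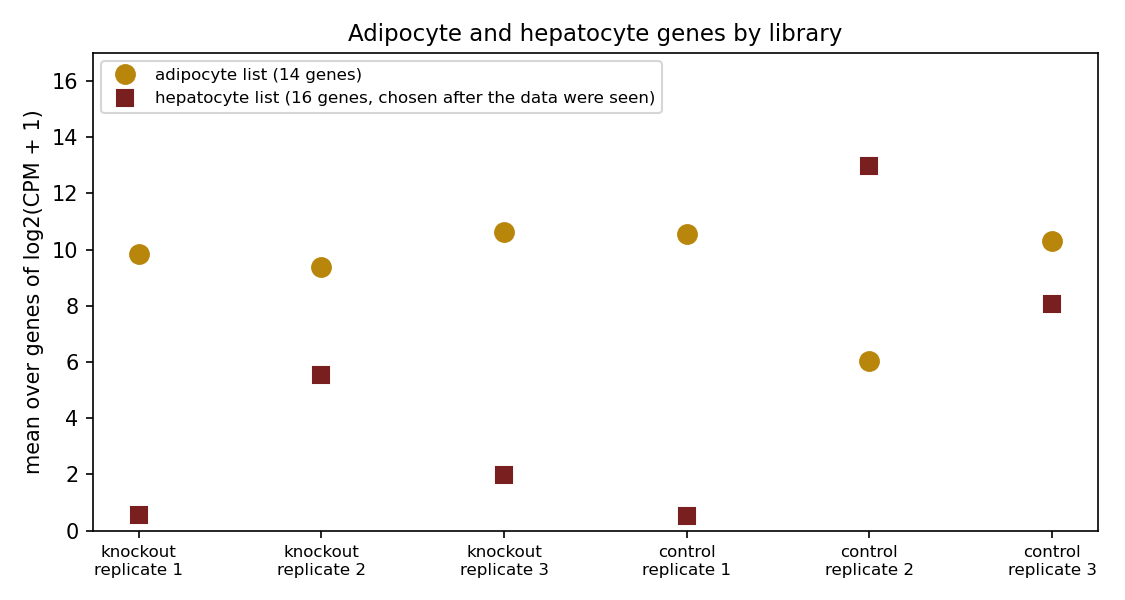
The mean of log2(CPM + 1) over the genes of the adipocyte list (circles) and of the hepatocyte list (squares) is plotted for each of the 6 libraries. In control replicate 2 the hepatocyte mean (12.96) is above the adipocyte mean (6.02), and in the 5 other libraries it is below.

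All comparisons with all 6 libraries therefore set 3 fat libraries against 2 fat libraries and 1 with a liver profile. Leaving out control replicate 2 was planned as part of leaving out each library in turn. Log2 fold changes and medians that moved by over 1.5 times, or changed sign or call, without control replicate 2 are given beside those of all 6. Those fits still hold control replicate 3 and knockout replicate 2, with hepatocyte list means of 8.05 and 5.55 log2(CPM + 1). Values without control replicate 2 are therefore not free of liver transcripts.

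The first comparison concerns the deleted gene. Pdcd1 (chromosome 1, 94038305 to 94052553, minus strand, mm10) had 19, 19 and 5 counts in knockout replicates 1 to 3 and 13, 0 and 0 counts in control replicates 1 to 3, against a detection floor of 3 counts per library. Its log2 fold change, knockout over control, was 1.46 ± 1.46 (SE) with an edgeR adjusted p of 0.803, and 1.02 ± 1.45 without control replicate 2 (adjusted p 0.852). A lower level in the knockouts was not detectable at this depth. Whole fat also holds T cells, which Lyz2-Cre does not target, so this count does not check the genotype labels. Of the receptor's ligands, Cd274 (PD-L1) had 15.7 ± 2.11 CPM (SD, n = 3) in knockouts and 14.4 ± 7.95 in controls (log2 fold change 0.11 ± 0.52 SE, edgeR adjusted p 0.971; −0.27 without control replicate 2), and Pdcd1lg2 (PD-L2) had 0, 7 and 1 counts in knockouts and 0 in each control.

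The study names the kinase ULK1, the ubiquitin ligase subunit FBXO38 and the endoplasmic reticulum stress sensor IRE1α. Ulk1 had 39.0 ± 4.79 CPM in knockouts and 57.0 ± 36.4 in controls (log2 fold change −0.55 ± 0.51 SE, 0.08 without control replicate 2), and Fbxo38 36.3 ± 1.22 and 38.2 ± 7.55 (−0.08 ± 0.26 SE, −0.22 without it). Ern1, which encodes IRE1α, had 13.6 ± 5.80 and 19.3 ± 15.1 CPM (−0.50 ± 0.63 SE), and its sign changed to 0.37 ± 0.45 without control replicate 2, the library with the highest Ern1 value (36.6 CPM). Xbp1, the transcription factor whose mRNA IRE1α splices, had 183 ± 10.4 and 289 ± 99.6 CPM (−0.66 ± 0.40 SE, −0.44 without that library). The chaperone gene Hspa5 had 631.5 ± 163 and 536.5 ± 232 CPM (0.24 ± 0.51 SE, and 0.65 ± 0.36 without control replicate 2, where it was highest at 796 CPM). With 1 library left out its log2 fold change ranged from 0.0056 to 0.65. Ddit3, the stress transcription factor CHOP, had 18.8 ± 0.618 and 12.3 ± 3.11 CPM, with each knockout above each control (0.62 ± 0.30 SE). The edgeR adjusted p-values over all genes were 0.782 for Ulk1, 0.960 for Fbxo38, 0.855 for Ern1, 0.642 for Xbp1, 0.931 for Hspa5 and 0.567 for Ddit3, so none of these differences passed the test. Lyz2, the lysozyme gene of the Cre driver and a macrophage marker, had 1945, 2334 and 376 CPM in knockouts and 299, 123 and 369 in controls (2.56 ± 0.85 SE, edgeR adjusted p 0.560). DESeq2 called Lyz2 with all 6 libraries (adjusted p 0.0418) and without control replicate 2 (0.0426).

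The next question was which genes differed between myeloid PD-1 knockout and control fat. Among higher values, Saa3 (chromosome 7, 46711998 to 46715700), an acute-phase protein of inflamed fat, had 33.6 ± 6.14 CPM (SD, n = 3) in knockouts and 5.03 ± 2.05 in controls, a log2 fold change of 2.75 ± 0.40 SE. Trac (chromosome 14, 54220521 to 54224206), the constant region of the T cell receptor alpha chain, had 12.99 ± 2.93 and 1.91 ± 0.538 CPM (2.76 ± 0.43 SE). The leukocyte receptor genes Slamf7 (19.9 ± 10.5 and 1.86 ± 0.533 CPM) and Slamf8 (10.5 ± 5.79 and 0.612 ± 0.283 CPM) and the sorting nexin gene Snx20 (20.5 ± 8.58 and 2.67 ± 1.25 CPM) had log2 fold changes of 3.40, 4.06 and 2.92. Among lower values, Nt5e (chromosome 9, 88327197 to 88372092), the surface enzyme CD73 that makes adenosine, had 3.55 ± 0.185 and 13.7 ± 4.20 CPM (−1.95 ± 0.38 SE). The prolactin receptor gene Prlr (chromosome 15, 10177238 to 10349180) had 9.19 ± 2.26 and 49.9 ± 30.5 CPM (−2.44 ± 0.50 SE). Lcn2, the iron-carrier-binding protein lipocalin-2, had 13.9 ± 6.70 and 72.7 ± 20.7 CPM (−2.39 ± 0.50 SE), and the mitochondrial tRNA gene mt-Te 3.97 ± 0.212 and 31.6 ± 21.5 CPM (−2.99 ± 0.54 SE). Among the genes of this paragraph, those near the floor in one group are given as counts only. Gpr50 had 723, 195 and 96 counts in knockouts and 0, 0 and 3 in controls, the synaptic vesicle gene Syt1 0, 2 and 0 against 93, 169 and 48, and the water channel gene Aqp4 0, 1 and 0 against 20, 112 and 40.

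None of these 12 genes passed the edgeR quasi-likelihood test, which called 0 of 15928 genes at an adjusted p under 0.05 (smallest 0.560), with 1377 genes at an unadjusted p under 0.05, 697 higher and 680 lower. Without control replicate 2 it called 0 of 16729 genes (smallest adjusted p 0.540, 1499 at an unadjusted p under 0.05). The 12 genes were chosen for no overlap between groups, so leaving out a library could not turn their signs. In that fit Saa3 stood at 3.13 ± 0.32 SE, Nt5e at −2.16 ± 0.28 and Prlr at −1.80 ± 0.28. DESeq2 called 530 genes with all 6 libraries, 241 higher and 289 lower, and 482 without control replicate 2, 369 higher and 113 lower, while limma-voom called 0 in both settings. All 12 genes were among the DESeq2 calls in both settings, but they were picked by p on the same counts, so these calls are not independent support. Of the 289 lower calls, 214 (74.0%) were at least 5 times as high in control replicate 2 as in knockout replicate 1 and control replicate 1, against 10 of the 113 (8.85%) without that library, and 257 genes were called in both settings in the same direction. Knockout and control values did not overlap for 1520 genes with knockouts above and 894 with knockouts below, 15.2% of those tested, where 10% is expected by chance. Genes can move together across libraries, and the spread of that share by chance was not measured, so 15.2% does not show an effect of genotype. On simulated counts with the spread of these libraries, edgeR called 0 of 50 genes changed 16-fold with all 6 libraries and 48 of 50 without control replicate 2. DESeq2 with all 6 called 4, 15, 41 and 48 of 50 genes changed 2-, 4-, 8- and 16-fold, together with 101 of 15708 unchanged genes. Without control replicate 2 it called 5, 36, 46 and 49 of 50, with 80 of 16509 unchanged genes. Unchanged genes thus made up a far larger share of its simulated calls than the 0.05 threshold names.

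**Figure D2:**
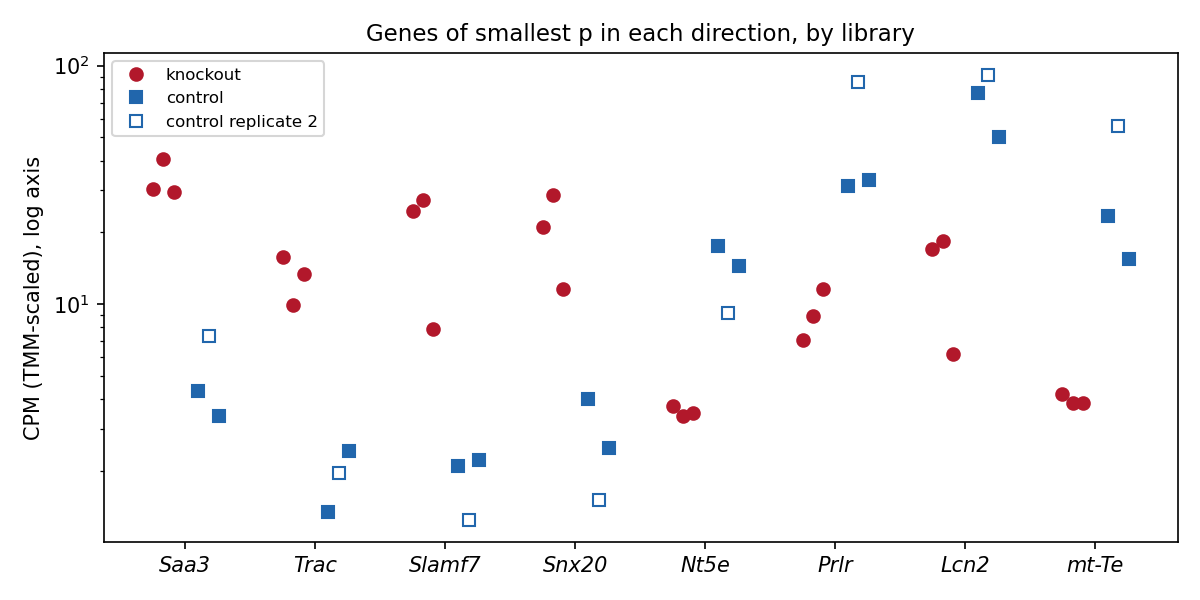
CPM on a log axis is plotted for 8 of the 12 genes of smallest p, with knockout libraries as circles, control libraries as filled squares and control replicate 2 as open squares. Saa3 lies between 29.6 and 40.7 CPM in knockouts and between 3.41 and 7.33 in controls, and Nt5e between 3.40 and 3.76 in knockouts and between 9.21 and 17.5 in controls.

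Macrophage genes were higher in the knockout group, mainly in replicates 1 and 2. The 15 measured macrophage markers averaged 7.27, 7.60 and 5.68 log2(CPM + 1) in knockout replicates 1 to 3 and 5.46, 4.27 and 5.19 in control replicates 1 to 3, with a median log2 fold change of 2.04 and 15 of 15 members above 0. Adgre1, which encodes the macrophage surface protein F4/80, had 268, 379 and 49.3 CPM in knockouts and 28.9, 12.1 and 33.5 in controls, and Fcgr1, Tyrobp and Itgam had log2 fold changes of 2.70, 2.32 and 2.55. Genes of lipid-associated macrophages had a median of 1.52 with 16 of 16 above 0, among them the lipid receptor gene Trem2 (236, 322 and 57.6 CPM against 21.2, 3.31 and 11.3), Itgax (178, 146 and 39.8 against 14.4, 2.33 and 13.7), the proton pump subunit gene Atp6v0d2 (5.54) and Cd9 (1.70). Lysosome genes had a median of 1.15 with 16 of 20 above 0, among them Ctsk (3.82), Gusb (1.88), Hexa (1.501) and Psap (2.05). Limma's camera test with a preset correlation gave adjusted p-values of 2.44e-08 for both macrophage lists and 5.96e-05 for lysosome genes, and each call was lost (adjusted p = 0.524 with an estimated correlation). The medians without control replicate 2 were 2.02, 1.95 and 1.16. The lysosome median was 0.76 without knockout replicate 2. By edgeR no member passed over all genes tested, and adjusted over the list alone 9 macrophage, 7 lipid-associated, 0 lysosome and 0 alternatively activated macrophage genes did. DESeq2 over all genes called 5, 7, 4 and 0 of them, and 8, 8, 5 and 0 without control replicate 2. The share of counts from all genes with a mitochondrial symbol also separated the groups, at 2.64% to 3.89% in knockouts and 5.45% to 9.08% in controls. A narrower list of mitochondrially encoded genes had been fixed as a sign of sample quality. Alternatively activated macrophage genes were not past the camera threshold (adjusted p 0.708), with a median of −0.30 and a test direction upward, which turned downward without control replicate 2 (−0.74, adjusted p 0.202). Of these, Arg1 (−5.98, and −1.71 without that library) and Timd4 (−2.86 and −0.83) were highest in control replicate 2, at 2437 and 12.2 CPM. They were next highest in control replicate 3, at 79.5 and 2.02 CPM. Stab1 (1.25) and Folr2 (1.63) were higher in knockouts 1 and 2.

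Other lists of immune genes also had medians above 0. The list means of MHC class II (6.05 to 6.93 log2(CPM + 1) in knockouts, 3.97 to 5.37 in controls), T cell (1.69 to 2.25, 1.15 to 1.38), mast cell (1.827 to 2.88, 0.253 to 1.802), dendritic cell (1.98 to 2.14, 1.24 to 1.90), checkpoint (2.88 to 3.51, 2.04 to 2.78) and NK genes (1.13 to 1.39, 0.934 to 1.085) were higher in each knockout than in each control. Knockout replicate 3 lay among the controls in the B cell (3.09, 3.87 and 1.78 in knockouts against 1.585, 2.07 and 2.34 in controls), pro-inflammatory (2.87, 2.70 and 1.87 against 1.915, 1.598 and 2.34) and interferon lists (4.55, 4.354 and 4.18 against 3.295, 4.350 and 4.02). The mitochondrial share of counts was lower in each knockout than in each control (2.64% to 3.89% against 5.45% to 9.08%). MHC class II antigen presentation genes had a median log2 fold change of 2.33 with 10 of 10 members above 0, among them the protease gene Ctss (638 ± 347 CPM against 84.1 ± 17.9, SD, n = 3), H2-DMb1 (76.6 ± 27.5 against 13.1 ± 9.57), H2-DMa (2.05) and H2-Ab1 (2.39). T cell genes had a median of 1.05 with 13 of 15 above 0, with Trac, Il7r (4.07), Cd2 (1.19) and Trbc2 (1.11) at the smallest p. B cell and plasma cell genes had a median of 1.99 with 12 of 14 above 0, among them Cd22 (3.81) and Cd79a (2.69). Mast cell and eosinophil genes had a median of 2.05 (7 of 7 above 0), dendritic cell genes 0.19 (8 of 9), immune checkpoint genes 1.27 (11 of 12, with Havcr2 at 3.48 and Btla at 1.43) and pro-inflammatory cytokines and chemokines 0.92 (13 of 19, with Saa3, Ccl4 at 2.97, Tnf at 2.14 and Ccl5 at 0.98). Camera adjusted p-values were 1.49e-08 for MHC class II, 0.000197 for T cell, 0.000727 for B cell, 0.00113 for mast cell and checkpoint, 0.0179 for dendritic cell and 0.0318 for pro-inflammatory genes, and each call was lost (adjusted p = 0.524 with an estimated correlation). The dendritic cell and pro-inflammatory calls were lost without control replicate 2 as well, at medians of 0.47 and 0.39 and adjusted p-values of 0.0658 and 0.0629, and without control replicate 1, at medians of 0.25 and 0.72 (0.248 and 0.155). The B cell call was lost without control replicate 1 (median 1.42, 0.0510) and on FPKM (1.04, 0.135). The checkpoint call was lost on FPKM (0.41, 0.0761) and without controls 2 and 3 (0.77, 0.105). The dendritic cell call was also lost without any 1 of the 3 knockouts (medians 0.35, 0.30 and 0.23, adjusted p 0.0584, 0.0876 and 0.15) and with no filter (0.20, 0.0605). It was kept without control replicate 3 (0.82, 0.0151). The pro-inflammatory call was lost without knockout replicate 1 (0.52, 0.174) or 2 (0.69, 0.0640). Interferon response genes (median 0.25, camera adjusted p 0.0704) and NK and cytotoxic genes (0.40, 0.253) passed without control replicate 2, with medians of 0.62 and 0.62, and these calls were lost too (adjusted p = 0.502 with an estimated correlation). Interferon genes also passed on FPKM (0.31, adjusted p 0.0446) and NK genes with no filter (0.45, 0.0231). The lowest interferon and NK medians with 1 library left out were 0.13 and 0.19. Without controls 2 and 3 the medians were 1.10 and 0.82. Oas1a (1.67), Oasl2 (1.68), Klrd1 (1.497) and Prf1 (1.74) were among the members of the interferon and NK lists. Adjusted over the list alone, 8 MHC class II, 3 B cell, 2 T cell and 1 pro-inflammatory genes passed by edgeR and 0 genes of the 5 other lists, against 0 over all genes. DESeq2 over all genes called 5 MHC class II, 3 B cell, 2 T cell, 1 checkpoint (Havcr2) and 1 pro-inflammatory (Saa3) genes. With control replicate 2 left out it called 6, 4, 3, 2 and 2 genes of these lists, 2 interferon genes and 1 dendritic cell gene.

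The mean of the cell cycle list was higher in each knockout library (2.71 to 4.20 log2(CPM + 1)) than in each control (1.78 to 2.42), and that of matrix genes mainly in knockout replicates 1 and 2. The matrix list averaged 7.78, 8.43 and 6.96 log2(CPM + 1) in knockouts and 5.98, 3.96 and 7.09 in controls, and the fibroblast list 6.25, 6.56 and 5.82 against 4.99, 3.59 and 5.93. The mitochondrial share of counts was 2.64% to 3.89% against 5.45% to 9.08%. Cell cycle genes had a median log2 fold change of 1.95 with 15 of 16 above 0, and Cdc20 (5.402 ± 1.73 CPM against 0.816 ± 0.426, SD, n = 3), Cdk1 (13.2 ± 7.17 against 2.26 ± 1.06), Ccnb2 (2.92) and Ccnb1 (2.79), regulators of mitosis, had the smallest p. Extracellular matrix and fibrosis genes had a median of 1.64 with 16 of 18 above 0, among them the growth factor gene Tgfb1 (120 ± 64.9 against 29.5 ± 14.2 CPM), the gelatinase gene Mmp2 (2.50) and the collagen genes Col6a3 (2.21) and Col3a1 (1255, 3685 and 601.5 CPM against 69.2, 60.5 and 594). Preadipocyte and fibroblast genes had a median of 1.04 with 13 of 14 above 0, among them Lum (2.65), Fap (2.01) and Pdgfra (1.17). Camera adjusted p-values were 1.86e-09, 3.31e-06 and 0.000197 for these lists, and each call was lost (adjusted p = 0.524 with an estimated correlation). Leaving out control replicate 2 gave medians of 2.27, 1.23 and 0.54. Col3a1 was low in control replicate 1 (69.2 CPM) as well as in control replicate 2 (60.5 CPM). The fibroblast median was 1.58 without control replicate 3. Adjusted over the list alone 11 cell cycle genes passed by edgeR and 0 of the other lists did, against 0 over all genes. DESeq2 over all genes called 5 cell cycle genes, 1 fibroblast gene (Lum) and 0 matrix genes, and 11, 1 and 0 without control replicate 2.

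**Figure D3:**
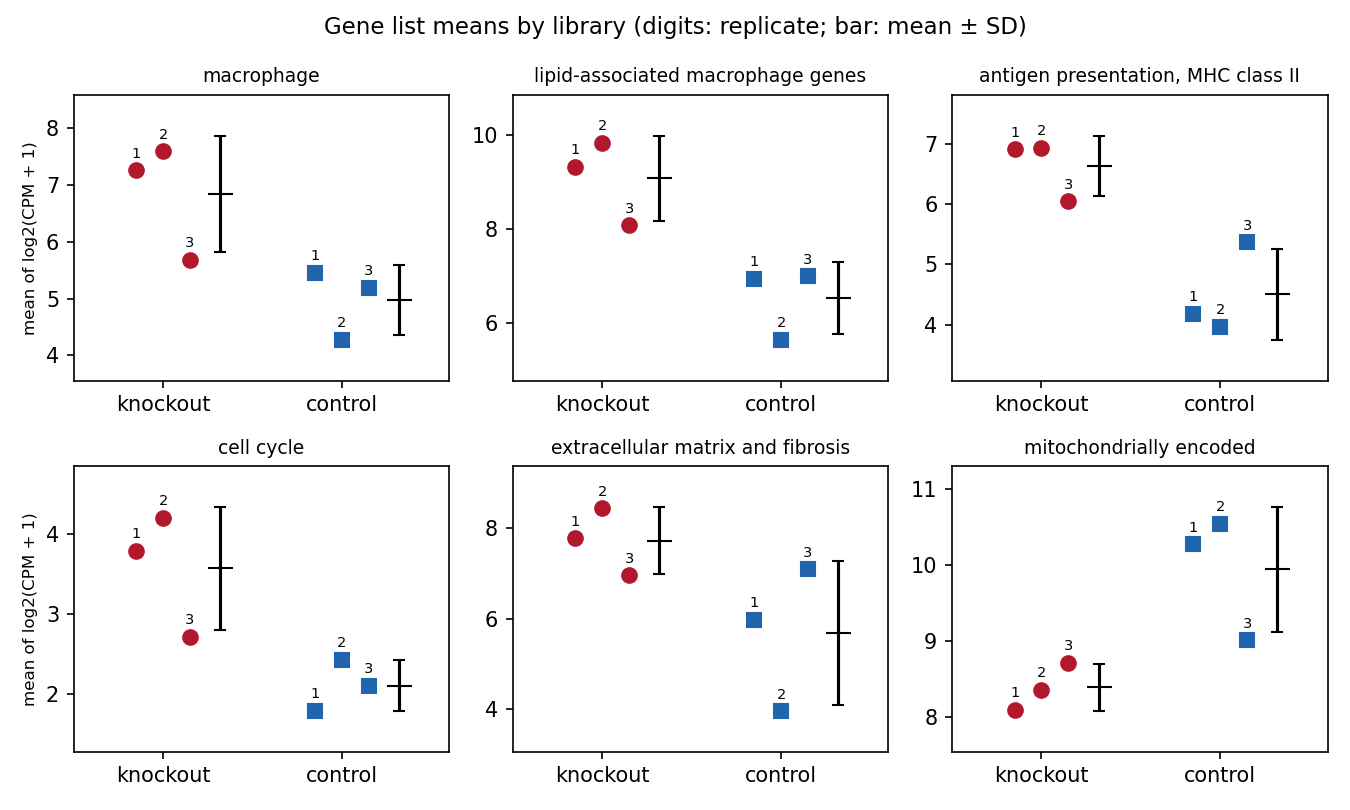
The mean of log2(CPM + 1) over each of 6 gene lists is plotted per library, with digits giving the replicate and bars the mean ± SD of 3 libraries. Macrophage genes average 7.27, 7.60 and 5.68 in knockouts, and knockout replicate 3 is the lowest knockout in 5 of the 6 lists. Mitochondrially encoded genes average 8.09 to 8.71 in knockouts and 9.01 to 10.5 in controls.

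Lists of mitochondrial and oxidative genes had medians below 0, and the mean of the mitochondrially encoded list was lower in each knockout than in each control. That list was fixed as a sign of sample quality. The 12 measured mitochondrially encoded genes had a median log2 fold change of −1.66 with 12 of 12 below 0, among them mt-Nd5 (1671 ± 418 CPM against 4831 ± 854, SD, n = 3) and mt-Atp6 (28.9 ± 6.40 against 176 ± 134). All genes with a mitochondrial symbol, including tRNA genes outside the list, took 2.64%, 3.19% and 3.89% of counts in knockouts and 9.08%, 6.90% and 5.45% in controls. Nuclear oxidative phosphorylation genes had a median of −0.83 with 20 of 22 below 0, among them Uqcrc2 (−1.22) and Ndufa4 (−1.47, and −0.98 without control replicate 2). Fatty acid oxidation genes had a median of −1.16 with 16 of 16 below 0, among them Ppara (1.13 ± 0.0117 against 21.6 ± 29.0 CPM) and Acadvl (−1.39), both highest in control replicate 2 and at −2.09 and −0.73 without it. Oxidative stress genes had a median of −0.75 with 11 of 14 below 0, among them Gclc (−2.59) and Sod1 (−1.56), both highest in control replicate 2, at 303 and 1794 CPM, and at −0.84 and −0.61 without it. Camera adjusted p-values were 2.98e-10, 1.08e-05, 1.08e-05 and 0.0140, and each call was lost (adjusted p = 0.524 with an estimated correlation). Without control replicate 2 the medians were −1.36, −0.55, −0.54 and −0.26, and the oxidative stress call was lost (adjusted p 0.258). It was also lost without control replicate 1 (0.0544), knockout replicate 3 (0.0514) or controls 2 and 3 (0.0537). Control replicate 3 was close to the knockouts in the nuclear lists. Oxidative phosphorylation averaged 6.76, 6.54 and 7.48 log2(CPM + 1) in knockouts and 7.88, 7.93 and 6.81 in controls. Fatty acid oxidation averaged 6.64, 6.41 and 6.94 against 7.44, 8.38 and 6.91, and oxidative stress genes 6.91, 6.996 and 7.03 against 7.41, 8.29 and 6.86. Erythrocyte genes (median −2.42, 8 of 8 below 0, camera adjusted p 0.000727) and neutrophil genes (−2.99, 5 of 6 below 0, 0.0209) were lower as well, and both calls were lost (adjusted p = 0.524 with an estimated correlation). Both lists were highest in control replicate 1, where Alas2, the first enzyme of heme synthesis in red cells, had 552 CPM against 11.7 to 196 in the other libraries, and S100a9 had 85.2 CPM against 0.621 to 22.3, and both calls were lost without it (medians −0.25 and −0.66, adjusted p 0.112 and 0.238). The neutrophil call was also lost on FPKM (−1.13, 0.0667). Adjusted over the list alone, 0 genes of these 6 lists passed by edgeR, as over all genes. DESeq2 over all genes called 4 mitochondrially encoded genes, 2 neutrophil genes, Ppara and Alas2, and without control replicate 2 called 4, 0 and the same last genes.

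Lists on endoplasmic reticulum stress, autophagy, insulin signalling, fat synthesis, lipolysis, thermogenesis and hypoxia did not pass the camera test on counts of all 6 libraries. The IRE1-XBP1 branch had a median log2 fold change of −0.16 (adjusted p 0.518), with Sdf2l1 (1.15) and Herpud1 (−2.002) as its members of smallest p. Herpud1 had 728.6 CPM in control replicate 2 and 66.4 to 96.7 in the others. Its value without that library was −0.19. The PERK-ATF4 branch had 0.16 (0.510), with Fgf21 (−2.42, and −1.38 without control replicate 2), Atf3 (3.12), the cystine transporter gene Slc7a11 (2.73) and Ddit3. Genes of the ATF6 branch and chaperones had −0.12 (0.753). Without control replicate 2 the last list turned to 0.53 and passed (adjusted p 0.00335, lost at adjusted p = 0.512 with an estimated correlation), and the 2 other branches changed sign to 0.16 and −0.12 without passing. Autophagy genes had −0.16 (adjusted p 0.109, −0.02 without control replicate 2, and −0.26 at 0.0409 without control replicate 3), with the lysosomal regulator gene Tfeb at 1.37 ± 0.33 SE. Insulin signalling genes had −0.11 (0.541), with the insulin receptor gene Insr at −1.0035 and the phosphatase gene Ptpn1 at 0.96, and passed without control replicate 2 (−0.27, adjusted p 0.0156, lost at adjusted p = 0.502 with an estimated correlation). Fatty acid and triglyceride synthesis (−0.19, 0.562, and −0.12 without control replicate 2), lipolysis (0.21, 0.431, and −0.27 without it), thermogenic genes (0.99, 0.0860) and hypoxia genes (−0.23, 0.541) did not pass on counts of all 6 libraries. The hypoxia median ranged from −0.25 to 0.18 with 1 library left out. Thermogenic genes passed on FPKM with all 6 libraries (1.63, adjusted p 0.0109) and without control replicate 2 and liver genes (1.09, 0.0435). Among thermogenic genes Ucp1, the uncoupling protein of brown fat, had 2.78, 2.14 and 10.2 CPM in knockouts and 0, 0 and 0.367 in controls. Adjusted over the list alone, 0 genes of these 9 lists passed by edgeR, as over all genes. DESeq2 over all genes called the thermogenic genes Ucp1 and Otop1 (higher in knockouts) and Elovl3 (lower). By edgeR Elovl3 stood at −6.08, with 205 CPM in control replicate 2, and at −2.64 without that library. Elovl3 had 11.8 CPM in control replicate 3 and 2.02 in control replicate 1. DESeq2 also called the hypoxia gene Egln3 (lower, −2.37 by edgeR, and −1.48 without control replicate 2), but not without that library. Egln3 was highest in control replicate 2, at 33.4 CPM. With control replicate 2 left out DESeq2 called Ucp1, Otop1, another hypoxia gene, Car9 (higher), Tfeb, Atf3 and 1 insulin signalling gene.

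Several lists had a median, mean and test of differing sign. Adipocyte genes had a median of −0.04 and an upward test (adjusted p 0.361), and without control replicate 2 were lower at −0.57 (adjusted p 0.0156, lost at adjusted p = 0.629 with an estimated correlation). Adipokine genes had a median of −0.21 and an upward test (0.708), which turned downward without that library (−0.16, 0.159). Endothelial genes had a median of 0.23, a mean of −0.29 and an upward test (0.440), and −0.26 without control replicate 2 (0.0367, lost at adjusted p = 0.502 with an estimated correlation and at 0.0642 with liver genes left out too). Cholesterol synthesis genes had a median of 0.35, a mean of −0.40 and an upward test (0.588), and 0.43 without control replicate 2 (0.0178, lost at adjusted p = 0.629 with an estimated correlation). Mesothelial genes had a median of 0.23, a mean of −0.89 and a downward test (0.0708), and passed without knockout replicate 2 (median −3.20, adjusted p 1.65e-06). The keratin genes Krt8 and Krt18 had 427 and 296 CPM in control replicate 2 (−5.64 and −5.78, and −2.96 and −3.00 without it). In control replicate 3, which also held liver transcripts, they had 42.8 and 29.7 CPM, against 8.88 and 3.37 in control replicate 1. Smooth muscle and pericyte genes (0.53, adjusted p 0.0872, and 0.12 without control replicate 2), skeletal muscle genes (0.80, 0.0620, and 0.30 without it) and dissection and cold stress genes (0.51, 0.0704) did not pass, with Fos at 232 CPM in knockout replicate 1 against 1.97 to 90.7 in the others. Smooth muscle genes passed without knockout replicate 1 (median 0.62, adjusted p 0.0447) or control replicate 3 (1.10, 0.0104) and on FPKM (0.91, 0.0446). Skeletal muscle genes passed without knockout replicate 1 (0.86, 0.00955), knockout replicate 2 (0.89, 0.0238) or control replicate 1 (1.24, 0.0229) and with no filter (0.84, 0.0422). Cold stress genes passed without knockout replicate 2 (0.47, 0.0467), knockout replicate 3 (0.77, 0.0177) or control replicate 3 (2.003, 0.00113), without controls 2 and 3 (1.57, 0.00322) and on FPKM (0.55, 0.0382). Adjusted over the list alone, 1 skeletal muscle gene (Tnni2) and 0 genes of the 7 other lists passed by edgeR, against 0 over all genes. Tnni2 was near the floor, at 0.556, 0.842 and 1.05 CPM in knockouts and 0, 0 and 0.0733 in controls. DESeq2 over all genes called Tnni2, Krt8 and Krt18, and without control replicate 2 Tnni2, 1 adipokine gene and 1 cold stress gene.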

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

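The settings that leave out control replicate 2 together with liver genes or with control replicate 3, DESeq2 and limma-voom without control replicate 2, limma-voom with sample weights and the estimated correlation without control replicate 2 were chosen after the data were seen. The count of 0 genes from edgeR held under each edgeR and limma setting run, including DESeq2's size factors, no filter, FPKM values, each left-out library and the title number as a term, and DESeq2 gave 530 (241 higher, 289 lower) and without control replicate 2 482 (369 higher, 113 lower). On simulated counts of the same spread with all 6 libraries, DESeq2 called 101 of 15708 unchanged genes. Beside these it called 4, 15, 41 and 48 of 50 genes changed 2-, 4-, 8- and 16-fold. In the same simulation edgeR called 0 of the unchanged and 0 of the changed genes. Pdcd1 kept a positive sign in 17 settings, between 0.040 without controls 2 and 3 and 6.63 without control replicate 1, where both controls left have 0 counts, and did not pass the filters on CPM and FPKM, which give it no value. The 19 gene lists were 14 to 23 with 1 library left out (14 without control replicate 1), 19 to 23 under other camera settings, 0 with an estimated correlation with or without control replicate 2, 0 by fry and 3 by fry's mixed p. Over lists and settings, 449 values kept direction and call, 98 lost the call, 30 gained one and 44 changed direction, and over named genes 348 kept both, 26 gained a DESeq2 call and 20 changed sign. Named genes that changed sign had no call under any setting run. Without control replicate 2 and liver genes, without controls 2 and 3, by DESeq2 and limma-voom without control replicate 2, and by limma-voom with sample weights, Cd274 stood at −0.28, −0.22, −0.27, −0.28 and −0.20, Ulk1 at 0.059, 0.71, 0.074, 0.16 and 0.054, and Ern1 at 0.35, 0.73, 0.36, 0.31 and 0.23. With 1 library left out they ranged from −0.27 to 0.39, −0.91 to 0.079 and −0.90 to 0.37, and Fbxo38 from −0.22 to 0.015. For lists, direction here and in the counts above is that of the test, and the values given are medians, whose sign can differ from it. For example, 0.22 for alternatively activated macrophage genes went with a downward test. Lists changed direction as follows, first without control replicate 2 and liver genes, then without controls 2 and 3. The last value is with an estimated correlation without control replicate 2. The IRE1-XBP1 branch stood at 0.15, 0.37 and 0.16, the PERK-ATF4 branch at −0.13, −0.17 and −0.12, ATF6 targets at 0.52, 0.46 and 0.53 (and −0.12 upward by fry), alternatively activated macrophage genes at −0.68, 0.22 and −0.74, lipolysis at −0.29, −0.24 and −0.27, adipokines at −0.36, −0.44 and −0.16 (−0.16 with genes of 1 list), adipocyte genes at −0.58, −0.68 and −0.57 (−0.13 with genes of 1 list) and endothelial genes at −0.25, −0.32 and −0.26, and fatty acid and triglyceride synthesis at 0.53 without controls 2 and 3. With 1 library left out the medians ranged from −0.38 to 0.16 for IRE1-XBP1, −0.12 to 0.31 for PERK-ATF4, −0.37 to 0.53 for ATF6, −0.74 to 0.32 for alternatively activated macrophages, −0.40 to −0.0088 for fatty acid synthesis, 0.0076 to 0.50 for cholesterol synthesis, −0.27 to 0.56 for lipolysis, −0.27 to 0.17 for insulin signalling, −0.72 to 0.56 for adipokines, −0.57 to 0.46 for adipocyte and −0.26 to 0.56 for endothelial genes. The cause was not tested beyond leaving out the library with the liver profile. Depth limits Pdcd1, with 0 to 19 counts. The spread between libraries limits the rest with all 6 libraries, at a biological coefficient of variation of 0.685. Without control replicate 2 it was 0.502, and edgeR called 18, 41 and 48 of 50 simulated genes at 4-, 8- and 16-fold. For that fit the spread was not shown to explain the 0 calls.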

Other observations

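The tests of the patterns in this part were chosen after the results were seen, including their thresholds, except the counts over other splits of the libraries. Transcripts of neighbouring organs were few. The 3 lists with under 5 measured members were not tested, and summed counts in knockout replicates 1 to 3 and control replicates 1 to 3 were 98, 186, 71, 1080, 355 and 325 for 20 epididymis genes, 1939, 722, 530, 648, 54 and 396 for 11 genes of testis germ cells, and 90, 93, 10, 292, 16 and 15 for 6 lymph node stroma genes. The epididymal secretory gene Crisp1 made up 1033 of the 1080 counts in control replicate 1, the germ cell sum was mostly Sycp3 (1874 counts in knockout replicate 1), and Cxcl13, a chemokine of B cell follicles, had 258 counts in control replicate 1 and 5 to 80 in the others.

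With only 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split gave 0 genes by edgeR and the highest other split 0, so 10 of the 10 splits gave as many. At an unadjusted edgeR p under 0.05 the real split had 1377 genes. Knockout replicates 1 and 2 with control replicate 3, set against the rest, had 2044, and the remaining splits had 61 to 771. The real split gave 19 gene lists and the highest other 20, with 3 splits at 19 or more, and 530 DESeq2 genes against 421 in the highest other, with 1 split as large.

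The liver profile of control replicate 2 may come from liver RNA in place of fat RNA, by a tissue or label exchange. The median adipocyte-list gene stood at 4.32% of its median in the 5 other libraries, below the 5% bound, which was set after this value was seen. A minor share of liver RNA in a fat sample is argued against, since only 2 of the 14 adipocyte genes, Acsl1 (118%) and Cebpa (122%), reached 50% of that median, and hepatocytes express both. The labels give no liver group, so no biological explanation was tested, and which tissue was sampled stays open.

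Liver transcripts also stood at a median of 7.55% of control replicate 2 in control replicate 3 and 1.48% in knockout replicate 2, over 171 genes. Reads of control replicate 2 assigned to other samples would keep these genes in 1 ratio, and chi-square per degree of freedom was 317 and 67.3. RNA of the same liver carried over before library preparation cannot be told apart from another liver source, since the robust SD of the log2 ratio was 0.463 and 0.466 and the spread that preparation adds is not known. In control replicate 2, control replicate 3 and knockout replicate 2, Mup22 had 58313, 4121 and 4 counts, Mup13 6713, 15 and 10, and Mup-ps19 4259, 15 and 4. In control replicate 3, Mup22, Mup13 and Mup-ps19 thus stood at 5.86%, 0.185% and 0.292% of control replicate 2. In knockout replicate 2 they stood at 0.00605%, 0.131% and 0.0828%. These genes were singled out after their values were seen, and they are near-identical paralogs that can share reads, so they were not taken to decide between the sources.

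Macrophage genes were high in knockout replicates 1 and 2 and lower in knockout replicate 3. Scaling between libraries is argued against, since with total counts alone the median difference was 1.78 on the log2 scale. Adipocyte genes were lower in knockout replicates 1 and 2 than in 3 (median −1.04, quartiles −1.43 and −0.591) and preadipocyte and fibroblast genes higher (0.484, upper quartile 1.08), as a lower share of adipocytes would give. As the whole explanation it is argued against, since it would raise other cell types alike and the macrophage median of 1.58 (quartiles 1.39 and 2.45) stood above endothelial (−0.00044, upper quartile 0.142) and smooth muscle genes (−0.22, upper quartile 0.155). All knockout libraries carry the same genotype label, so genotype as labelled does not account for the difference among them. Whether genotype raises macrophage genes over controls stays open. The exact two-sided permutation p of the list mean was 0.1 with all 6 libraries and 0.2 without control replicate 2, and with so few libraries it cannot go below 0.1, so this test could not decide it. Knockout replicate 3 and control replicate 3 have adjacent title numbers, apart from those of the other libraries. Their macrophage means were 5.68 and 5.19 log2(CPM + 1). With a term setting these libraries apart from the others, 761 genes had an unadjusted edgeR p under 0.05, against 1377 without it. The term also uses a degree of freedom, which by itself can lower this count. The labels do not say what the numbers mean, and a grouping behind them was not tested for these genes.

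One hypothesis was that the Cre allele in the Lyz2 locus lowers Lyz2 relative to other macrophage genes. Lyz2 minus the mean of the other macrophage genes was 3.92, 3.85 and 3.08 in knockouts and 2.97 and 3.58 in control replicates 1 and 3 on the log2 scale, a difference of 0.345, opposite in sign to the hypothesis. With control replicate 2 (2.88) included the difference was 0.478, with an exact two-sided permutation p of 0.2 (smallest possible 0.1).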
